A study of Rattus norvegicus with 26 samples.

How the data were processed

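Total RNA of the thoracic aorta was measured on 26 1-colour (Cy3) Agilent rat arrays: 8 of rats dosed with saline, 6 each with low-dose and high-dose Songling Xuemaikang capsule (SXC) and 6 with valsartan. Per the labels' protocols, RNA was extracted with TRIzol from each aorta separately, amplified and labelled with the Quick Amp kit, and the rats were killed after 28 days. SXC was given in the morning and around noon and valsartan in the afternoon, per the labels. The hour of tissue collection is not given in the sources used here. Group and replicate number were taken from the sample titles.

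Per the file headers, the authors scanned the arrays and quantified them with Agilent Feature Extraction 11.0.1.1. The intensity values used here, the processed signal, were background-subtracted and detrended within each array by that program, per the file headers, and were not normalised between arrays. The deposited files also hold median spot and local background intensity and spot flags (values of 0 or 1). The authors' deposited table of all samples holds log2 values. Its method is not given in the sources used here; every column has nearly the same distribution (medians 5.75 to 5.76), as quantile normalisation gives, the values are not centred per gene, and each column correlated with its own array's scanner values. It served as an alternative.

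Control spots and spots marked as outliers by the scanner software were left out, and spots of the same probe were averaged. Levels are log2 of the processed signal minus each array's 75th percentile over probes outside controls. A probe counted as well above background on an array when at least 0.5 of its spots did, and the 23744 of 30367 probes well above background on at least 6 of the 26 arrays were tested. Probes were named by matching their RefSeq accession, without version, to the GRCr8 gene table: 18005 probes matched 1 symbol (15168 different symbols), 0 matched several and 12362 have no symbol here. The file headers name the older rn4 build, so no coordinates are given.

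Groups were compared in all 6 pairs with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend, 2-sided) in 1 fit over the 26 arrays with no covariates, and Benjamini-Hochberg adjusted p under 0.05 per comparison was taken as a call. All adjusted p-values for single genes come from this limma test. Data were read with the package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9. Gene lists were tested with camera, at its preset inter-gene correlation of 0.01 and again with an estimated correlation, on 1 probe per gene (the brightest on average), for the 33 lists fixed before the data were examined, all with at least 5 measured genes. Camera compares a list with the other genes measured, so a list called lower is lower relative to them. Members of a list were counted from the test over all probes and adjusted over the list alone.

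The rule for named genes was also fixed before the data were examined. It takes, per comparison, among called probes with a symbol that were well above background on every array of the brighter group and were the gene's brightest probe, the 10 largest rises and the 10 largest falls (6 and 6 for the comparisons of valsartan with SXC). It adds up to 4 members with the smallest p of each called list, of which the text gives examples, and, against saline, Agtr1a, Agt, Ace, Nos3, Edn1, Ucp1, Adipoq, Acta2, Col1a1, Nr1d1 and Dbp. Symbols beginning with LOC or RGD were passed over, and 4 genes the rule takes are not reported here. List members that moved against their list, the further members of 2 lists in the other observations, and clock genes shown again under a block were named after their values were seen.

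Where a probe was not well above background on any array of a group, the difference is given as at least N-fold: the bright group's mean level against the mean over the dim group's arrays of the higher of the lowest signal among probes well above background and the probe's own. Such folds rest on normalised log2 means. No probe was saturated on all arrays of a group in a named result.

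Slide, scan day and detector gain were read from the files as batches: 9 slides, 5 scan days and 2 gain levels. Slide was fitted as a random block (correlation 0.21), and scan day, slide and gain as fixed blocks where a batch held more than 1 group. The labels' replicate numbers were fitted as a block as an alternative. Shared calls were set against 20 simulations of unchanged groups sharing a simulated saline group, and against independent lists. They were also set against saline arrays split into sets of 4. Other splits of the arrays of each comparison were refitted 100 times.

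The fits were tested on simulated data with the real means and spreads, with 200 of 23744 probes changed and the oxidative phosphorylation list raised 2-fold besides. Of probes changed 2-fold and 4-fold, 54% and 78% were recovered for high-dose SXC against saline, 46% and 74% for low-dose SXC against saline, 41% and 83% for valsartan against saline, 41% and 79% for high-dose against low-dose SXC, 38% and 73% for valsartan against low-dose SXC and 44% and 73% for valsartan against high-dose SXC. Between 4.26% and 7.58% of the calls were unchanged probes. The simulated noise was independent between arrays, with no effect of slide, scan day or gain, so this share does not carry over to the real comparisons.

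The alternatives tried were normexp background correction (offset 50) on the median spot signal, in place of the mean spot signal, which was not used here; quantile normalisation; the authors' table; no filter on dim probes; only the 7278 probes well above background on all 26 arrays; the compared groups alone; the blocks named above; array weights; 1 probe per gene; an unadjusted p under 0.05 with a fold of at least 1.5; an estimated correlation for lists; and leaving out each array in turn. Fits without doubtful arrays, within scan days, with saline as 3 averages and with gain as a block were added after the data were seen. No sample was left out of the comparisons.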

Results

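RNA levels were measured in the thoracic aorta of male spontaneously hypertensive rats, a strain with inherited high blood pressure. For 4 weeks the rats were dosed by mouth with saline (7.5 mL per kg, n = 8 arrays), with Songling Xuemaikang capsule (SXC), a herbal preparation, at a low dose (236.25 mg per kg, n = 6) or a high dose (708.75 mg per kg, n = 6), or with valsartan, a blocker of the angiotensin II type 1 receptor (21.6 mg per kg, n = 6). The series text gives 8 rats for valsartan, and 6 valsartan arrays were analysed here. Each sample was read on a 1-colour array with 30367 probes outside the controls, of which 23744 were well above background on at least 6 of the 26 arrays and were tested. Levels are log2 intensities relative to the array's 75th percentile, and the number of arrays limits the precision: the median standard error of a log2 fold change was 0.30 against saline and 0.33 between treated groups.

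The arrays differed in brightness and in when they were scanned. Between 67.3% and 76.2% of probes were well above background on the saline arrays, 70.4% to 77.0% on the low-dose SXC arrays, 28.9% to 79.6% on the high-dose SXC arrays and 32.5% to 56.5% on the valsartan arrays. All 8 saline arrays were scanned on a single day, 82 days after the last treated array. With 0 scan days holding both saline and treated arrays, scan batch and treatment cannot be told apart in any comparison with saline. The 6 valsartan arrays and 4 of the high-dose SXC arrays, 10 arrays in all, were scanned at a lower detector gain (323 to 325 V) than the other arrays (353 to 354 V). The first principal component held 62.4% of the variance after quantile normalisation. On it saline arrays lay from -80.8 to -54.4, treated arrays at the higher gain from -18.8 to 19.5 and lower-gain arrays from 36.6 to 68.4. High-dose arrays 1 and 2, at the higher gain, thus lay apart from the rest of their group. Saline arrays 4 and 8 each lay close to an average of 2 other saline arrays (SD 0.16 and 0.10 on the log2 scale), closer than any treated array lay to such an average (0.23 or more). Arrays 1 and 5, 2 and 6, and 3 and 7 of saline deviated together, so that n = 8 may overstate the independent saline samples behind every SD, SE and call against saline. With saline as the 3 averages of these pairs, a fit chosen after the data were seen, 9780, 5708 and 9920 probes passed for high-dose SXC, low-dose SXC and valsartan.

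**Figure D1:**
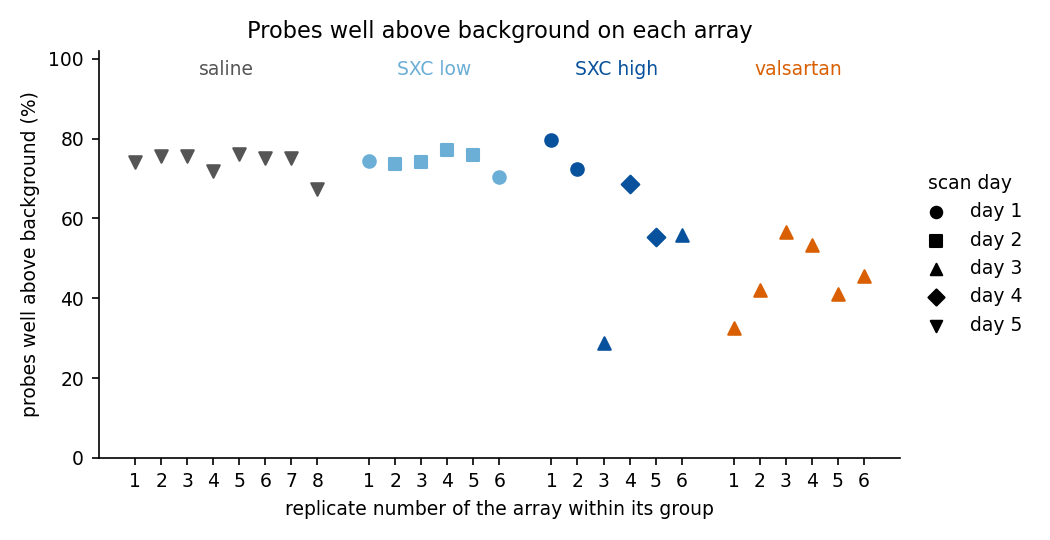
Percentage of probes well above background on each of the 26 arrays, by group and replicate number, with the marker showing the scan day. Saline arrays lie between 67.3% and 76.2% and valsartan arrays between 32.5% and 56.5%.

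High-dose SXC was compared with saline to ask what the higher dose changed in the aorta. Haemoglobin RNA was far lower in the high-dose group: Hbb-b1, a beta-globin, had a level of 0.90 ± 0.78 (SD, n = 6) against 7.14 ± 0.73 (SD, n = 8) in saline, a log2 change of -6.23 ± 0.44 (SE). The lists of macrophage, endothelial, white fat and mitochondrial genes were lower by camera at its preset correlation, and 0 lists passed with an estimated correlation (smallest adjusted p = 0.16). The angiotensin receptor Agtr1a, of the type that valsartan blocks, fell (-2.22 ± 0.19). Its second rat copy Agtr1b rose (2.27 ± 0.24). In all, 13549 probes (57.1%) passed the limma test, 8465 higher and 5084 lower, naming 4592 genes that were higher and 3101 that were lower.

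The largest falls were those of the red cell genes Hbb-bs (-6.49), Hbb-b1, Hbe2 (-5.98), Hbb (-4.87), Hba-a1 (-4.86) and Alas2 (-4.42), with the carbonic anhydrase Car2 (-5.93) and the protease inhibitor Slpi (-4.49). Cd52 (at least 24.2-fold) and Add2 (at least 8.95-fold) also fell and were not well above background on any high-dose array. Of the 12 measured markers of neutrophils and red cells, 8 fell and 2 rose, and the list was lower by camera (adjusted p = 0.00075, and 0.387 with an estimated correlation). The risers were Elane, neutrophil elastase (6.80 ± 0.59), and the chemokine receptor Cxcr2 (2.40). The 10 largest rises were in genes that were faint or not above background in saline: Lrfn2 (8.11), Adam32 (7.72), Sftpc (7.36), Ikzf2 (7.24), Svs3a (7.07), the olfactory receptor Or6c3d (7.02) and Rph3a (6.80). The others, Grm8 (at least 95.3-fold), Dlx1 (at least 63.9-fold) and Dbndd1 (at least 61.0-fold), were not well above background on any saline array.

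Of 17 macrophage markers, 15 fell and 0 rose (median -1.91, adjusted p = 1.94e-11, and 0.16 with an estimated correlation), among them the protease Ctss (-3.53 ± 0.22), the scavenger receptor Cd163 (-2.74) and the complement genes C1qb (-2.52) and C1qa (-2.71). Among 10 genes of MHC class II presentation, 5 fell, led by RT1-Da (-3.47) and Cd74 (-3.32), while RT1-DOb and Ciita rose (adjusted p = 0.000239, and 0.244 with an estimated correlation). Ciita (0.94), the master regulator of the class, turned to -0.44 after quantile normalisation and -0.31 in the authors' values. Of 25 interferon response genes, 14 fell, including Irf7 (-3.79) and Rsad2 (-4.17), and 4 rose, including Gbp5 (1.60) (adjusted p = 0.00619, and 0.16 with an estimated correlation). In the list of 21 inflammatory cytokines and adhesion molecules 9 fell, such as Cxcl1 (-2.27) and Il6 (-2.30), and 3 rose, namely the adhesion molecule Vcam1 (1.72), the chemokine Ccl4 and the selectin Sele (adjusted p = 0.0291, and 0.387 with an estimated correlation). Ccl4 was well above background on 3 of 6 high-dose arrays and 1 saline array. Sele turned from 1.13 to -0.14 after quantile normalisation and -0.12 in the authors' values, and the list's median of -0.59 became 0.15 after normexp background correction.

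The renin-angiotensin list fell (9 of 13 genes fell and 2 rose; adjusted p = 0.0433, and 0.16 with an estimated correlation). Agt, the precursor angiotensinogen (-2.33 ± 0.55), and Cma1, a mast cell chymase that makes angiotensin II (-3.98 ± 0.48), were lower. Agtr1b and the peptidase Thop1 (1.62) were higher, and the converting enzyme Ace did not pass (0.42 ± 0.22). Of 15 endothelial markers 9 fell, including the junction genes Cldn5 (-3.40), Esam (-2.89) and Pecam1 (-2.68), while Cdh5, the endothelial cadherin, and Sox18 rose (adjusted p = 0.00313, and 0.387 with an estimated correlation). Nos3, endothelial nitric oxide synthase (-1.33 ± 0.27), and Edn1, the precursor of endothelin 1 (-2.51 ± 0.38), were lower. Acta2, smooth muscle actin (-0.49 ± 0.38), and Col1a1, a chain of collagen I (-0.12 ± 0.18), did not pass.

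White fat markers (10 of 19 fell and 0 rose; median -1.42, adjusted p = 0.00759, and 0.659 with an estimated correlation) included Cfd (-3.08) and Pck1 (-3.83). Fat RNA varied widely among the saline arrays: Adipoq lay at 2.05 and 2.06 on arrays 1 and 5, inside the high-dose range of 1.12 to 3.76, and at 6.22, 6.27 and 5.55 on arrays 3, 7 and 8, which raise the saline mean. Adipoq fell by 1.42 (adjusted p = 0.044) while Ucp1, the uncoupling protein of brown fat, did not pass (-1.57 ± 0.86). In fatty acid oxidation 12 of 24 genes fell and 0 rose, with Eci1 (-2.65) and Acaa2 (-3.34) as examples (adjusted p = 0.000909, and 0.64 with an estimated correlation). In oxidative phosphorylation 19 of 33 fell, such as Atp5f1b (-2.36), and 1 rose (adjusted p = 0.00117, and 0.659 with an estimated correlation). Among 18 glucocorticoid targets 12 fell and 2 rose, with Mt1, a metallothionein (-2.65), and Tsc22d3 (-2.77) falling and Per1 and Hif3a rising (adjusted p = 0.000182, and 0.212 with an estimated correlation). Of 24 antioxidant genes 12 fell, such as Ftl1, a ferritin chain (-1.12), and Cat, catalase (-1.66), and 3 rose (adjusted p = 0.00367, and 0.212 with an estimated correlation). The clock genes Nr1d1 (2.14 ± 0.30) and Dbp (1.58 ± 0.27) rose.

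**Figure D2:**
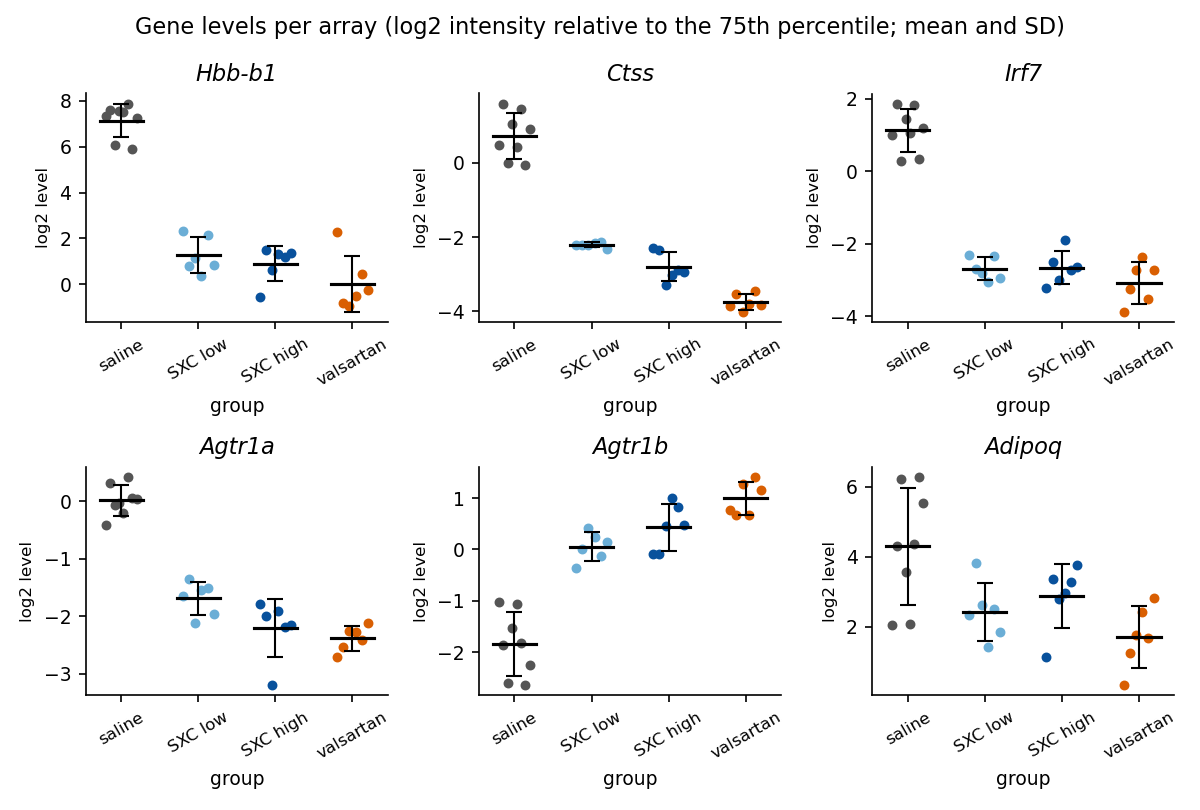
Levels of 6 genes on every array (log2 intensity relative to the array's 75th percentile, points) with the group mean and SD (bars) in saline (n = 8), low-dose SXC, high-dose SXC and valsartan (n = 6 each). Hbb-b1 averages 7.14 in saline and 0.90 with high-dose SXC, and Agtr1a falls where Agtr1b rises.

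Camera called 12 of 33 lists in this comparison, all of them lower. With an estimated correlation it called 0 (smallest adjusted p = 0.16, and 6 lists at an unadjusted p under 0.05). Adjusted over the list alone, the counts were the same except for glucocorticoid targets (3 rose, 12 fell) and antioxidant genes (4 rose, 12 fell). The balance of higher and lower probes depended on the scaling: 62.5% of called probes were higher with the 75th percentile, 76.7% after normexp, 41.7% after quantile normalisation and 41.9% in the authors' values, where the median of all probes tested shifted by 0.25, 0.55, -0.23 and -0.21. With detector gain as a block, a fit chosen after the data were seen, 6505 probes were called.

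Low-dose SXC was compared with saline to ask what the lower dose changed. Several genes given for the high dose moved in the same direction: Hbb-b1 fell by 5.86 ± 0.44 (1.27 ± 0.79, SD, n = 6, against 7.14 ± 0.73, SD, n = 8), Ctss fell by 2.94 ± 0.22, Nos3 fell by 2.19 ± 0.27 and Agtr1a fell by 1.70 ± 0.19, while Agtr1b rose by 1.90 ± 0.24. Among the largest rises Dlx1 alone was shared with the high dose. In all 9408 probes (39.6%) passed, 5345 higher and 4063 lower, naming 3093 higher and 2738 lower genes. The largest falls were in Hbe2 (-6.55), Cd52 (-6.56), Car2 (-6.12), Hbb-bs (-6.07), Alas2 (-5.96), Hbb-b1, Slpi (-5.73), and the endothelial receptor Tek (-4.86). Hemgn (at least 62.5-fold) and Add2 (at least 36.1-fold) were not well above background on any low-dose array. The largest rises were in Rup2 (5.31), Ttr, the thyroid hormone carrier transthyretin (5.07), Hoxc12 (4.70), Isl2 (4.67), Psd2 (4.50), Tssk3 (4.45) and Hrg (4.31). Dlx1 (at least 24.4-fold), Slc38a4 (at least 9.58-fold) and Vgf (at least 5.13-fold) followed and were not well above background on any saline array.

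With the low dose, 14 of 17 macrophage markers fell and 0 rose (median -1.97, adjusted p = 9.53e-12, and 0.106 with an estimated correlation), and so did 7 of 10 genes of MHC class II presentation, with 0 rising (adjusted p = 2.13e-06, and 0.106). Of 12 blood cell markers 9 fell, among them Hba-a1 (-4.68), and Elane rose (adjusted p = 2.54e-07, and 0.132 with an estimated correlation). Of 15 endothelial markers 10 fell, such as Cldn5 (-3.77), and Cdh5 and Sox18 rose (adjusted p = 5.97e-05, and 0.163 with an estimated correlation). In the interferon list 12 of 25 fell, including Irf7 (-3.81) and Ifit3 (-3.37), and 2 rose, including Gbp5 (adjusted p = 0.00241, and 0.106 with an estimated correlation). In the inflammatory list 9 of 21 fell, including Il6 (-3.24) and Ccl5 (-1.99), and Vcam1 rose (adjusted p = 0.000877, and 0.163 with an estimated correlation).

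Fat and mitochondrial lists were lower with the low dose as well, against the same uneven saline arrays (Pck1 from -1.50 to 5.24 and Cfd from 1.13 to 4.78, highest on arrays 3, 7 and 8). There 14 of 19 white fat markers fell, such as Cfd (-3.00), Pck1 (-4.20) and Lpl, lipoprotein lipase (-2.85), and 0 rose (adjusted p = 0.000211, and 0.507 with an estimated correlation). In fatty acid oxidation 15 of 24 fell and 0 rose (adjusted p = 0.000114, and 0.507 with an estimated correlation). In oxidative phosphorylation 13 of 33 fell, such as Atp5f1b (-2.03), while Atp5pf (0.63) and Sdhc rose (adjusted p = 0.00751, and 0.756 with an estimated correlation). Of the glucocorticoid targets 13 of 18 fell, such as Mt1 (-3.15) and Tsc22d3 (-2.63), and 2 rose (adjusted p = 2.54e-07, and 0.106 with an estimated correlation). Of the antioxidant genes 9 of 24 fell and 2 rose (adjusted p = 0.0171, and 0.216 with an estimated correlation). Adipoq (-1.88 ± 0.60), Ucp1 (-2.40 ± 0.86), Edn1 (-2.40 ± 0.38) and Agt (-2.27 ± 0.55) fell and Nr1d1 rose (0.98 ± 0.30), while Dbp (0.13 ± 0.27), Acta2 (0.26 ± 0.38), Col1a1 (0.25 ± 0.18) and Ace (-0.18 ± 0.22) did not pass. The renin-angiotensin list was not called (7 of 13 fell and 2 rose, 8 fell adjusted over the list alone; adjusted p = 0.0585).

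Camera called 11 of 33 lists for the low dose, all of them lower. With an estimated correlation it called 0 (smallest adjusted p = 0.106, and 9 lists at an unadjusted p under 0.05). Adjusted over the list alone, the counts were the same except for white fat markers (15 fell), antioxidant genes (11 fell), fatty acid oxidation (17 fell) and oxidative phosphorylation (16 fell). The share of called probes that were higher was 56.8% with the 75th percentile, 64.2% after normexp, 54.0% after quantile normalisation and 53.3% in the authors' values, where the median of all probes shifted by 0.09, 0.24, 0.01 and 0.01. All low-dose and saline arrays were scanned at the higher gain, on different days. With saline taken as the 3 averages of arrays 1 and 5, 2 and 6, and 3 and 7, which deviated together from the means of their slides (r = 0.71, 0.66 and 0.87 across probes), and without arrays 4 and 8, 5708 probes were called. This fit was chosen after the data were seen.

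Valsartan was compared with saline, per the series text as the positive control. Hbb-b1 fell by 7.11 ± 0.44 (0.03 ± 1.22, SD, n = 6, against 7.14 ± 0.73, SD, n = 8), and Ctss fell by 4.48 ± 0.22. Agtr1a, the drug's target, fell by 2.40 ± 0.19 (-2.39 ± 0.22, SD, n = 6, against 0.01 ± 0.26, SD, n = 8), while Agtr1b rose by 2.84 ± 0.24. The fat and mitochondrial lists were lower by camera, but not with an estimated correlation (adjusted p = 0.549 to 0.697). The clock output gene Dbp was higher by 2.70 ± 0.27. In all 13876 probes (58.4%) passed, 7888 higher and 5988 lower, naming 4340 higher and 3544 lower genes. The largest falls were in Hbb-bs (-7.22), Hbb-b1, Hbe2 (-6.45), Hbb (-5.67), Pck1 (-5.64), Hba-a1 (-5.47), and Alas2 (-4.72). Car2 (at least 32.5-fold), Cd52 (at least 10.3-fold) and Cd74 (at least 9.30-fold) fell too and were not well above background on any valsartan array. The largest rises were in Lrfn2 (8.24), Ikzf2 (7.57), Elane (7.48), Sftpc (7.44), Adam32 (7.38) and Svs3a (7.35). Next came Dlx1 (at least 91.7-fold), Grm8 (at least 89.9-fold), Dbndd1 (at least 76.3-fold) and the olfactory receptor Or2a20 (at least 49.8-fold), which were not well above background on any saline array.

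In the renin-angiotensin list 8 of 13 genes fell with valsartan and Agtr1b and Thop1 rose (adjusted p = 0.0421, and 0.24 with an estimated correlation). Agt (-3.15 ± 0.55) was lower, Cma1 was at least 5.98-fold lower, and Ace did not pass (0.07 ± 0.22). Of 17 macrophage markers 16 fell and 0 rose (median -2.18, adjusted p = 1.93e-15, and 0.12 with an estimated correlation). Of 10 MHC class II genes 5 fell, such as RT1-Da (-3.95), and Ciita rose (1.01, but -0.61 after quantile normalisation and -0.46 in the authors' values; adjusted p = 4.38e-06, and 0.257 with an estimated correlation). Of 12 blood cell markers 8 fell and Elane and Cxcr2 rose, Cxcr2 (1.81) turning to -0.15 after quantile normalisation (adjusted p = 0.000428, and 0.407 with an estimated correlation). Of 15 endothelial markers 10 fell, such as Pecam1 (-2.78) and Cldn5 (at least 7.98-fold), and Cdh5 and Sox18 rose (adjusted p = 0.00153, and 0.378 with an estimated correlation). Nos3 was at least 1.52-fold and Edn1 at least 1.59-fold lower.

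Interferon genes went both ways with valsartan: 15 of 25 fell, such as Irf7 (-4.20) and Rsad2 (-4.15), and 5 rose, such as Gbp5 (1.70), and the list median of -0.81 became 0.15 after normexp (adjusted p = 0.0421, and 0.257 with an estimated correlation). Of 21 inflammatory genes 8 fell, such as Icam1 (-1.51) and Nfkbia (-1.63), and Vcam1, Ccl4 and Sele rose (adjusted p = 0.0241, and 0.407 with an estimated correlation). Ccl4 was well above background on 0 valsartan arrays, and Sele (1.27) turned to -0.03 in the authors' values and just below 0 after quantile normalisation. The list's median of -0.47 became 0.14 after normexp. White fat markers fell in 14 of 19 cases and rose in 0 (median -2.60, adjusted p = 0.000233, and 0.582 with an estimated correlation), and brown fat markers fell in 11 of 15, such as Pdk4 (-2.42), while Kng1 and Otop1 rose (adjusted p = 0.021, and 0.595 with an estimated correlation). Adipoq (-2.60 ± 0.60) and Ucp1 (-2.98 ± 0.86) were lower. In fatty acid oxidation 21 of 24 fell, such as Acaa2 (-4.20) and Hadhb (-3.17), and 0 rose (adjusted p = 8.6e-05, and 0.549 with an estimated correlation). In oxidative phosphorylation 19 of 33 fell, such as Sdhb (-2.59), and 1 rose (adjusted p = 0.00137, and 0.697 with an estimated correlation). Of 18 glucocorticoid targets 11 fell, such as Mt1 (-2.62), and Hif3a and Per1 rose (adjusted p = 0.000233, and 0.257 with an estimated correlation). Of 24 antioxidant genes 12 fell, such as Cat (-2.24), and 3 rose (adjusted p = 0.0038, and 0.257 with an estimated correlation). Nr1d1 rose (1.42 ± 0.30), while Acta2 (-0.83 ± 0.38) and Col1a1 (-0.26 ± 0.18) did not pass.

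Camera called 13 of 33 lists for valsartan, all of them lower. With an estimated correlation it called 0 (smallest adjusted p = 0.12, and 6 lists at an unadjusted p under 0.05). Adjusted over the list alone, the counts were the same except for blood cell markers (9 fell), white fat markers (15 fell) and oxidative phosphorylation (20 fell). The share of called probes that were higher was 56.8% with the 75th percentile, 78.2% after normexp, 38.1% after quantile normalisation and 38.8% in the authors' values, where the median of all probes shifted by 0.19, 0.70, -0.30 and -0.27. With detector gain as a block, 3256 probes were called, 3000 of them in the same direction as without it. That block rests wholly on high-dose SXC, the only group scanned at both gains.

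The treatments were also compared in what they shared. High-dose SXC and valsartan called 11200 probes in the same direction (6734 higher, 4466 lower), and 7008 probes went the same way in all 3 treated groups (3954 higher, 3054 lower). High-dose and low-dose SXC shared 7692 (4385 higher, 3307 lower), and low-dose SXC and valsartan shared 7564 (4269 higher, 3295 lower). Independent lists would share 2812 higher and 1282 lower for the first pair, 1906 and 870 for the second, and 1776 and 1025 for the third. Across probes, which are not independent replicates, the log2 changes of the pairs correlated with r = 0.93, 0.79 and 0.73 (covariance 1.94, 1.12 and 1.05). Unchanged groups simulated against a shared simulated saline group gave r = 0.43 (covariance 0.06) and 0 shared probes. That r follows from the group sizes, and with no probe changed few calls could be shared. The simulations therefore do not test the real saline arrays. With the saline arrays split into disjoint sets of 4, the pairs shared 8803, 5582 and 5562 probes (r = 0.89, 0.73 and 0.68). Saline arrays 1 and 5, 2 and 6, and 3 and 7 deviated together, so the sets may not be independent controls. The simulations likewise took the saline arrays as independent. All 3 comparisons also share the scan day of saline. The valsartan arrays and most high-dose arrays share the lower gain, and high-dose arrays 3 and 6 share the scan day of valsartan. The larger sharing of high-dose SXC and valsartan therefore cannot be told apart from batch.

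High-dose and low-dose SXC were compared to ask what the dose changed. The largest differences were in genes with faint or no signal at the low dose: Grm8 was higher at the high dose by 5.54 ± 0.86 (0.11 ± 1.82, SD, n = 6, against -5.43 ± 2.51, SD, n = 6). Then came Or8b8 (5.52), Svs3a (5.35), Dbndd1 (5.31), Ccdc134 (4.94), Rph3a (4.84), Or2a20 (4.83), Ly49i2 (4.79), Frmpd4 (4.75) and the stem cell factor Sox2 (4.65). The falls were smaller: Tcf21 (-1.74), Fbxo9 (-1.71), Ptprv (-1.61), the core clock gene Bmal1 (-1.59 ± 0.43), Fgl2 (-1.50), Slc22a2 (-1.33), Caprin1 (-1.32), Abcg3 (-1.29), Smo (-1.26) and Nr4a3 (-1.25). With scan day as a block Grm8 was at 0.17 ± 0.76 (SE). In all 5273 probes passed, 3989 higher and 1284 lower, naming 2197 higher and 702 lower genes.

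Of 8 T and B lymphocyte markers, 5 rose at the high dose and 0 fell (7 rose adjusted over the list alone), such as the T cell receptor genes Cd3g (3.44 ± 0.57) and Cd247, which was well above background on 0 arrays of either dose (adjusted p = 0.0118, and 0.848 with an estimated correlation). The contractile smooth muscle list was lower by camera (median -0.33, adjusted p = 0.0452, and 0.885 with an estimated correlation), though 0 of its 16 genes passed alone, also adjusted over the list alone. Lmod1 (-0.59 ± 0.22) and Myl9 (-0.55 ± 0.23) were its members nearest to passing. The cytosolic ribosomal protein list was lower as well (median -0.18, adjusted p = 0.0118, and 0.848 with an estimated correlation), but its median was 0.08 after quantile normalisation and 0.09 in the authors' values; 1 of its 33 genes fell, Rps2 (-0.48), also adjusted over the list alone. Camera called 3 of 33 lists and 0 with an estimated correlation (1 list at an unadjusted p under 0.05). With quantile normalisation and in the authors' values it called 0 lists (8 at an unadjusted p under 0.05 in each), the lymphocyte median being 0.53 and 0.46 and the contractile median -0.21 and -0.22.

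Scan days ran across this comparison, with 2 arrays of each dose scanned on a shared day. With scan day as a block limma called 0 probes (165 at an unadjusted p under 0.05). On the shared day alone 0 were called (477 at an unadjusted p under 0.05). Detector gain as a block left 0 (1014 at an unadjusted p under 0.05). These unadjusted counts lie below the share of 0.05 of the 23744 probes that chance gives. The scan day block rests on the 2 arrays of each dose on the shared day, and the SE of Per2 went from 0.12 to 0.19. The 0 calls therefore do not show that dose had no effect. With slide as a random block 1617 were called, and with slide as a fixed block, which compares 2 high-dose arrays with a single low-dose array on the 1 slide holding both doses, 16. Without high-dose array 4 the count was 3357 and without low-dose array 2 it was 3455. Of the 24 named genes that passed, 19 kept their direction with scan day as a block, 0 of them beyond 2 standard errors, and with gain as a block 22 did, 10 of them beyond 2 standard errors. On the shared day alone 19 did, 4 of them beyond 2 standard errors. Among the clock genes, looked at afterwards, Ciart was 1.97 with no block and 1.90 ± 0.45 with scan day as a block, Dbp 1.45 and 0.98 ± 0.33, and Per2 0.37 and 0.56 ± 0.19, while Bhlhe40 went from 1.86 to 0.29, Nr1d1 from 1.16 to 0.25 and Per1 from 1.08 to -0.12. All 6 were called with no block and 0 with it. The same held for Tef (0.86 and 0.91 ± 0.39), Nr1d2 (0.62 and 0.79 ± 0.41) and Bmal1 (-1.59 and -0.96 ± 0.73). As a list, the clock genes were not called by camera with no block (adjusted p = 0.12). Camera at its preset correlation gave them as higher with scan day as a block (median 0.25, adjusted p = 0.00124) and with gain as a block (median 0.43, adjusted p = 0.0378). The contractile list was lower with scan day as a block (adjusted p = 0.00124), with a smaller median (-0.19, against -0.33 with no block) and Lmod1 at 0.02 and Myl9 at -0.64, while the lymphocyte list (adjusted p = 0.233) and the ribosomal list (adjusted p = 0.16) were not called. With gain as a block the lymphocyte list was called (median 0.69, adjusted p = 0.00212), and the contractile list (median -0.09, adjusted p = 0.234) and the ribosomal list (adjusted p = 0.579) were not. The share of called probes that were higher was 75.6% with the 75th percentile, 81.4% after normexp, 44.9% after quantile normalisation and 44.2% in the authors' values, where the median of all probes shifted by 0.10, 0.37, -0.20 and -0.20.

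Valsartan and low-dose SXC were compared next. The clock genes differed most clearly: Per2, a repressor of the clock, was higher with valsartan by 1.77 ± 0.12 (1.98 ± 0.18, SD, n = 6, against 0.21 ± 0.19, SD, n = 6). Ciart was higher by 4.53 ± 0.31 and Tef by 2.03 ± 0.20, while Npas2 fell by 2.70 ± 0.32 and Bmal1 was at least 7.21-fold lower, being not well above background on any valsartan array. Of 15 clock genes, 7 rose and 4 fell (adjusted p = 0.00249, and 0.728 with an estimated correlation). Camera also gave the list as higher with scan day as a block (adjusted p = 0.000674) and with gain as a block (adjusted p = 0.00278), although its median was then -0.10 and -0.15. In all 5972 probes passed, 3233 higher and 2739 lower, naming 1857 higher and 1370 lower genes. The largest rises were in Or8b8 (6.13), Hsf2bp (6.10), Hivep1 (5.95), Dbndd1 (5.63), Svs3a (5.63) and Or2a20 (5.54), and the largest falls, after Bmal1, in Krcc1 (-2.77), Arvcf (-2.70), Npas2, Or8b59 (at least 2.01-fold) and Arsi (at least 2.20-fold).

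Of 17 macrophage markers, 8 fell with valsartan and 0 rose, such as the lysozyme gene Lyz2 (-1.94) and Ctss (-1.54) (adjusted p = 0.0005, and 0.728 with an estimated correlation). Of 17 heat shock genes 9 fell and 0 rose, such as the chaperones Hsph1 (-1.95) and Hspa8 (-0.66) (adjusted p = 0.00425, and 0.728 with an estimated correlation). Of 24 extracellular matrix genes 5 fell, such as the collagen Col5a1 (-0.91) and periostin, Postn (-0.99), and Thbs1, thrombospondin 1, rose (2.15) (adjusted p = 0.00788, and 0.778 with an estimated correlation). Of 33 ribosomal protein genes 7 fell, such as Rps2 (-0.66), and 0 rose (median -0.20, and 0.07 after quantile normalisation and 0.06 in the authors' values; adjusted p = 0.00249, and 0.778 with an estimated correlation). Of 8 lymphocyte markers 5 rose, such as Cd3g (3.92), and 0 fell (median 1.41, but -0.15 after quantile normalisation; adjusted p = 0.00788, and 0.728 with an estimated correlation). Adjusted over the list alone the counts were the same for clock and heat shock genes, 10 fell for macrophage markers, 6 fell for matrix genes, 5 fell for ribosomal genes and 1 fell for lymphocyte markers.

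No scan day held both valsartan and low-dose SXC arrays, so that a block on scan day rests on the high-dose arrays that link the days. With it 3 probes passed, those of Per2 (2.04), Ciart (4.98) and Angpt4, well above background on 0 valsartan arrays and not called with no block, the last named after its value was seen. Of 34 named genes that passed, 25 kept their direction and 6 lay beyond 2 standard errors: Per2, Ciart, Npas2 (-2.82 ± 0.59), Tef (2.18 ± 0.50), Bmal1 and Arsi. The largest rises ended near 0 or below: Or8b8 (-0.41), Hsf2bp (0.09), Hivep1 (-0.44), Dbndd1 (-0.38), Svs3a (0.08) and Or2a20 (-1.27). The macrophage, heat shock, matrix, ribosomal and lymphocyte lists were not called (adjusted p = 0.219, 0.175, 0.172, 0.724 and 0.585). The macrophage median went from -0.63 to -0.50, the heat shock median from -0.63 to -0.57 and the matrix median from -0.40 to -0.27, while the ribosomal median went from -0.20 to -0.05 and the lymphocyte median from 1.41 to -0.11. Of these lists gain as a block kept the macrophage list alone (adjusted p = 0.00278). With detector gain as a block, which also rests on the high-dose arrays, 3 passed, Per2, Ciart and Kcna6, the last likewise named afterwards. With slide as a random block 1840 passed. Camera called 6 of 33 lists, 2 with quantile normalisation, 2 in the authors' values and 0 with an estimated correlation (0 lists at an unadjusted p under 0.05). The share of called probes that were higher was 54.1% with the 75th percentile, 82.0% after normexp, 28.3% after quantile normalisation and 29.5% in the authors' values, where the median of all probes shifted by 0.03, 0.50, -0.24 and -0.23.

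Valsartan and high-dose SXC gave the fewest calls of the 6 comparisons with no block (325). With scan day as a block 399 were called here, against 0 for the SXC doses and 3 for valsartan against low-dose SXC. Gain as a block gave 1423, against 0 and 3. The SE of Per2, 0.12 in each with no block, was 0.15, 0.19 and 0.24 with scan day and 0.13, 0.17 and 0.21 with gain. The blocks thus estimate this comparison more precisely than the other 2, and these counts do not rank the differences between groups. The clock genes again led: Per2 was higher with valsartan by 1.40 ± 0.12 (1.98 ± 0.18, SD, n = 6, against 0.58 ± 0.13, SD, n = 6), Ciart by 2.56 ± 0.31 (1.67 ± 0.23, SD, n = 6, against -0.89 ± 0.64, SD, n = 6). Cry1 was higher by 1.99 ± 0.23 and Tef by 1.17 ± 0.20, while Npas2 fell by 1.98, Clock fell by 1.01 and Bmal1 was at least 2.40-fold lower. Of 15 clock genes 4 rose and 3 fell (6 rose and 7 fell adjusted over the list alone). Camera gave the list as higher (adjusted p = 0.0305, and 0.824 with an estimated correlation), although its median was -0.22 and its mean -0.02. In all 325 probes passed, 63 higher and 262 lower, and 4091 had an unadjusted p under 0.05; they named 47 higher and 165 lower genes. The other largest rises were in the cell cycle kinase Wee1 (1.46), Hars1 (1.31) and Adamts1 (1.12), and the other largest falls in Usp13 (-1.85), Pla2g7 (at least 1.25-fold), Taar7b (at least 1.75-fold), Ebf1 (at least 1.34-fold) and Or1e32 (at least 1.41-fold).

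**Figure D3:**
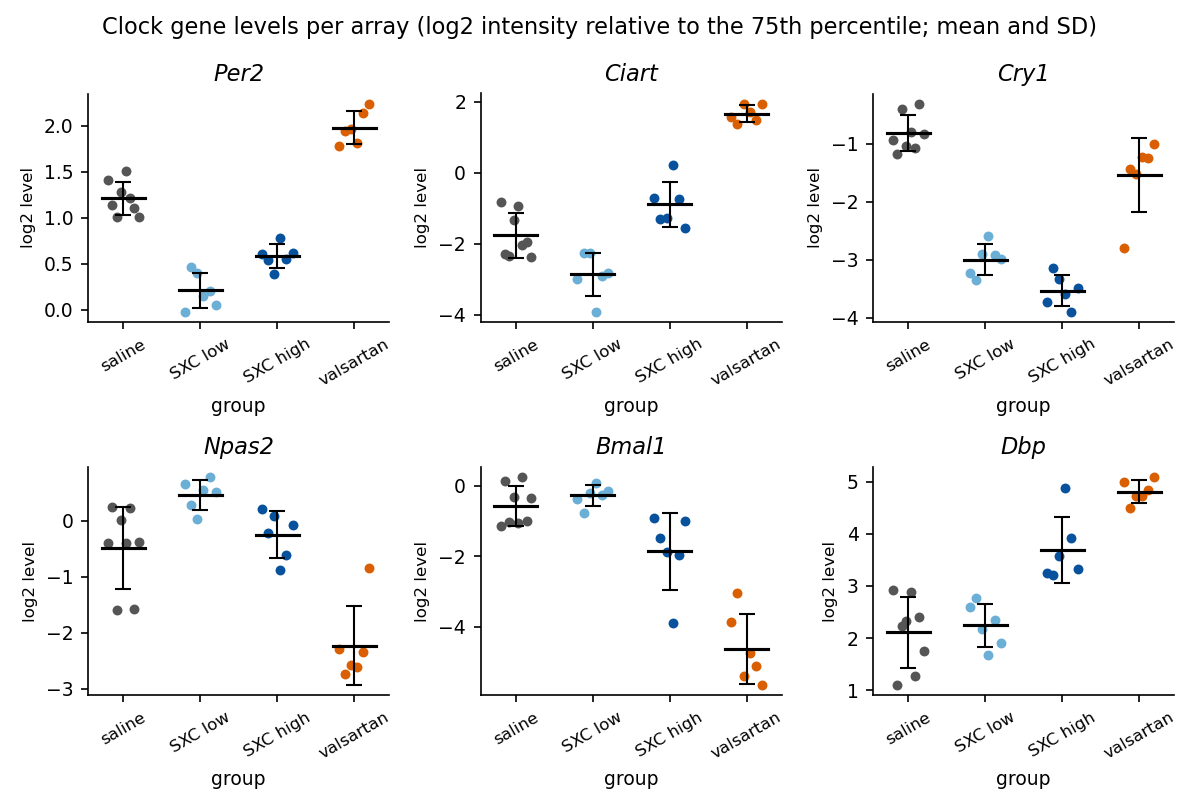
Levels of the clock genes Per2, Ciart, Cry1, Npas2, Bmal1 and Dbp on every array (log2 intensity relative to the array's 75th percentile, points) with the group mean and SD (bars) in saline (n = 8), low-dose SXC, high-dose SXC and valsartan (n = 6 each). Per2 averages 1.98 with valsartan, 0.58 with high-dose SXC and 0.21 with low-dose SXC.

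Macrophage markers were lower with valsartan than with high-dose SXC (2 of 17 fell and 0 rose, 8 fell adjusted over the list alone; adjusted p = 0.00136, and 0.746 with an estimated correlation), namely Ctss (-0.95) and Tyrobp (-0.85). In the MHC class II list 2 of 10 fell, Ctss and Cd74, which was well above background on 4 high-dose and 0 valsartan arrays, and 3 fell adjusted over the list alone (adjusted p = 0.0179, and 0.746 with an estimated correlation). Brown fat markers (median -1.05, adjusted p = 0.00392, and 0.746 with an estimated correlation) and white fat markers (median -0.84, adjusted p = 0.00637, and 0.934 with an estimated correlation) were lower by camera. The thyroid hormone deiodinase Dio2 was at least 1.63-fold lower and was the 1 brown fat gene that passed, also adjusted over the list alone, and 0 white fat genes passed (2 fell adjusted over the list alone). Cell cycle genes were higher as a list (median 0.42, adjusted p = 0.00136, and 0.746 with an estimated correlation), with 0 of 23 passing (2 rose adjusted over the list alone). So were calcium handling and potassium channel genes (median 0.21, adjusted p = 0.00637, and 0.746 with an estimated correlation), of which the calcium sensor Stim1 (0.57) rose (2 rose adjusted over the list alone).

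With scan day as a block, which here rests wholly on the day when the 6 valsartan arrays and 2 of the high-dose arrays were scanned, 399 probes passed. Per2 (1.48, adjusted p = 0.000354), Ciart (3.08, adjusted p = 0.000824), Npas2 (-2.24, adjusted p = 0.0107), Bmal1 (adjusted p = 0.0204, not well above background on any valsartan array) and Cry1 (1.87, adjusted p = 0.0285) kept their calls. Of 19 named genes that passed, all kept their direction beyond 2 standard errors, and 10 were still called. The calls of Tef (1.27 ± 0.32, adjusted p = 0.0535), Wee1 (0.97), Hars1 (1.53), Adamts1 (0.89), Usp13 (-1.49), Stim1 (0.74), Ctss (-0.64), Ebf1 and Cd74 ended. By camera at its preset correlation the calcium, clock, white fat and brown fat lists kept their calls (adjusted p = 0.0346, 0.0346, 4.3e-05 and 0.000522). The clock median was then 0.02. The macrophage, MHC class II and cell cycle lists did not keep theirs (adjusted p = 0.573, 0.357 and 0.0899). An estimated correlation was not tried with a block. The cell cycle median stayed at 0.41 (0.42 with no block), and the macrophage and MHC class II medians went from -0.45 to -0.33 and from -0.56 to -0.38. With gain as a block the clock list was not called (median -0.44, adjusted p = 0.183), nor was MHC class II (median -0.46, against -0.56 with no block, adjusted p = 0.137). The macrophage (adjusted p = 0.0445), cell cycle (adjusted p = 0.0354), calcium, white fat and brown fat lists were (adjusted p = 0.0297 for each of the last 3). On that day alone 5 probes passed, on the lower-gain arrays alone 4, with slide as a random block 4, and with gain as a block 1423. Left out 1 at a time, high-dose arrays 1 to 6 gave counts of 644, 183, 606, 125, 121 and 686, and valsartan arrays 1, 2, 4, 5 and 6 gave 886, 703, 168, 109 and 92. Camera called 7 of 33 lists and 0 with an estimated correlation (0 lists at an unadjusted p under 0.05). The share of called probes that were higher was 19.4% with the 75th percentile, 70.6% of the 17 called after normexp, 22.4% after quantile normalisation and 23.8% in the authors' values, where the median of all probes shifted by -0.10, 0.11, -0.06 and -0.05.

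**Figure D4:**
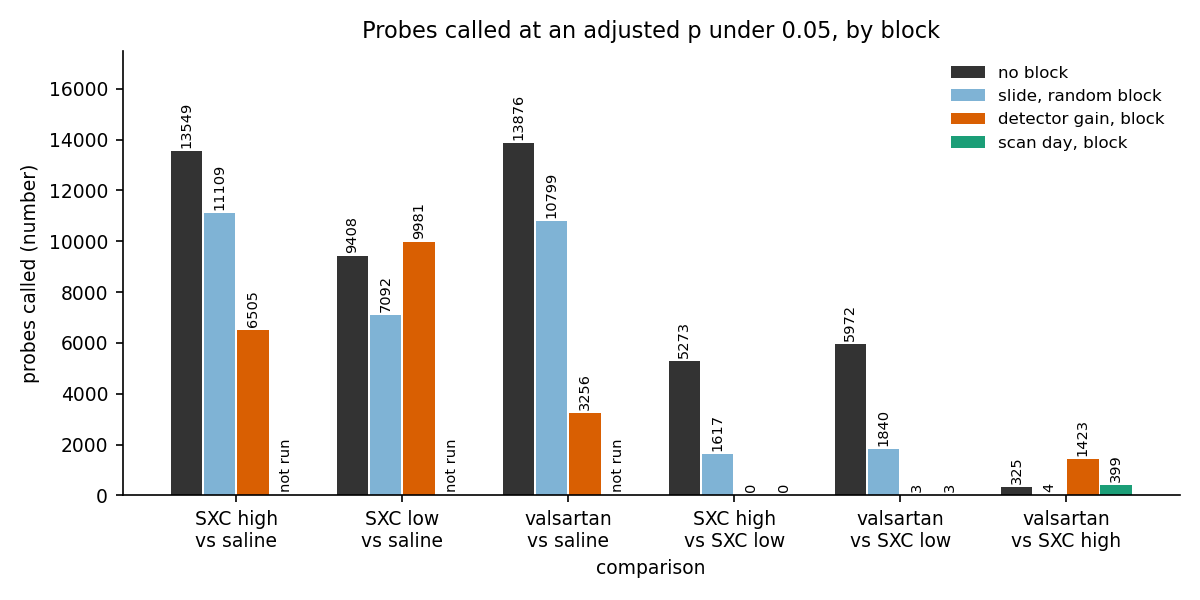
Number of probes called in each of the 6 comparisons (bars, from 0) with no block, with slide as a random block, with detector gain as a block and, between treated groups, with scan day as a block. For high-dose against low-dose SXC the counts are 5273, 1617, 0 and 0.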

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

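The tests of detector gain, of separate scanning and of the clock genes were chosen after the results were seen. So was the mix on probes well above background on all arrays. The splits, the red cell test and the mix on probes set aside were written down before their results.

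A single value was checked against the rest of its group by the gap to its neighbour over the group's range, for 154 genes named in the text and 2 measures of array brightness, in each of the 4 groups with a value on every array. Of 619 groups of values, 35 (5.65%) held a value far from the others, and chance flags about 1 in 20 groups. No array was left out for this, and the values cluster on a few arrays. Low-dose array 2 had 8 such values: Acaa2 (-0.75), Acta2 (5.63), Clock (-2.97), Gbp5 (0.69), Hadhb (0.76), Hoxc12 (-4.41), Sdhb (1.99) and Usp13 (-0.41). High-dose array 3 had 6, in Agtr1a (-3.20), Cd247 (-3.14), Ednrb (-3.23), Il6 (-3.24), Pla2g7 (-0.048) and Slpi (-3.33). All but Pla2g7 lie within 0.23 of the lowest level on that array (-3.37), a floor that limits how low a gene can read there. High-dose array 1 had 4, in Adipoq (1.12), Hbb-bs (-2.35), Hbe2 (-1.51) and Pecam1 (-1.26).

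The other treated arrays stood apart in few genes by the same gap. These were Bmal1 (-3.91) on high-dose array 4, Ifit3 (-2.71) on low-dose array 1, and Adra1d (2.02) and Ednrb (-4.83) on low-dose array 3. Among the valsartan arrays they were Cd163 (-3.83, near the lowest level of -3.93 there) and Cry1 (-2.80) on array 1, Kng1 (-6.14) and Otop1 (-0.34) on array 4, and Npas2 (-0.84) on array 6. Among the saline arrays they were Or8b8 (-8.37) and Svs3a (-3.39) on array 1, Hoxc12 (-4.25) on array 2, Cd3g (-1.06) on array 4, Rph3a (-4.53) on array 6, and Hrg (-8.09), Rup2 (-7.81) and Ttr (-6.89) on array 8.

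Splitting the arrays of each comparison differently asks whether chance alone could give as many probes. The splits cross scan days and gains, so they speak of chance alone and not of batches. In 4 comparisons no other split drawn reached the real count. The splits treat arrays as independent, although arrays of a group shared slides and scan days. Saline arrays 1 and 5, 2 and 6, and 3 and 7 also deviated together. These splits therefore cannot exclude chance among a few batches of arrays. Of 100 splits, 1, the real one, reached the count of high-dose SXC against saline (13549, highest other 11325), of low-dose SXC against saline (9408, highest other 4990), of valsartan against saline (13876, highest other 1253) and of valsartan against low-dose SXC (5972, highest other 737). For the 2 SXC doses 2 of 100 did (5273, highest other 5413), which does not separate dose from scan day. The larger split put high-dose arrays 1 and 2, scanned on day 1, with low-dose arrays 2 to 5, all of day 2, and with scan day as a block, on day 1 alone and with gain as a block 0 probes passed in limma (165, 477 and 1014 at an unadjusted p under 0.05). For valsartan against high-dose SXC chance cannot be excluded, since 11 of 100 splits reached 325 probes, though with scan day and with gain as a block 399 and 1423 passed. The highest, 1413, set valsartan arrays 3, 4 and 6 with high-dose arrays 4, 5 and 6 against the rest. That rest held high-dose arrays 1 and 2, at the higher gain. It also held high-dose array 3 and valsartan arrays 1, 2 and 5, with 28.9%, 32.5%, 41.9% and 41.2% of probes well above background. The 2 sides therefore also differ in gain and brightness.

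Large numbers of probes differed from saline in every treated group, and detector gain, separate scanning and leftover blood were weighed as sources. Gain does not account for all of it in the SXC groups. Low-dose SXC, scanned wholly at the gain of saline, called 9408 probes, and the 2 high-dose arrays at that gain called 10162. Valsartan called 3256 with gain as a block, 3000 of them called in the same direction without it. That block rests wholly on high-dose SXC, the only group scanned at both gains, on different scan days. It therefore cannot settle what gain does for valsartan. Separate scanning cannot be told apart from treatment, because 0 scan days held both saline and treated arrays. More blood left in the saline aortas may explain the fall of the globin genes, but 15 further red cell genes had medians of -0.28, -1.07 and -0.61 for high-dose SXC, low-dose SXC and valsartan (SE 0.40, 0.45 and 0.35), and the highest, -0.28, decides nothing. Of these 15 genes 5, 7 and 6 fell and 2, 1 and 2 rose, while Hbb-b1 averaged 7.14 in saline and 0.90, 1.27 and 0.03 in the 3 treated groups.

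Clock genes differed between valsartan and high-dose SXC, and a batch or a shifted clock phase at tissue collection could produce this. On scan day 3 alone, with 6 valsartan and 2 high-dose arrays at 1 gain, 7 of 7 called clock genes lay beyond 2 standard errors in the same direction. Of these 7 Ciart alone was called there. This speaks against scan day and gain, but the genes were chosen on arrays that include these. The high-dose side was arrays 3 and 6, array 3 having 28.9% of probes well above background, and the 2 groups still sat on separate slides. A shifted phase may contribute, as 6 of 7 went with their textbook phase and Cry1 did not. Of the 13 called over the list alone 9 did and 4, Cry1 and Nr1d1 among them, did not. The test set the genes in 2 opposite phases and leaves no place for a gene that peaks in between. Genes that went the other way therefore do not speak against a shift, and this stays undecided. The labels give different dosing times of day for SXC and valsartan and no hour of killing. The idea is a hypothesis found and tested on the same arrays.

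On bright probes saline array 8 lay close to an equal mix of saline arrays 2 and 3. Its SD around that mix was 0.105, against 0.50 around its nearest single array and 0.229 for the closest treated array. On probes set aside the SD was 0.193, with a best share of 0.52, against 0.318. Saline array 4 had an SD of 0.163 around a mix of arrays 1 and 2 (share 0.48), and 0.174 on probes set aside. Cd3g on array 4 (-1.06) lay above the other saline arrays (highest -2.85). Both probe sets held only probes well above background on all 8 saline arrays, so probes dim on array 8 were left out. Ttr, Rup2 and Hrg, picked as values apart, were lower on array 8 (-6.89, -7.81 and -8.09). The lowest on other saline arrays was -2.94, -4.36 and -6.36. An equal mix would not fall below both its arrays, though Rup2 and Hrg lie near the lowest level of array 8 (-8.22). Whether array 8 is such a mix stays undecided. No biological source of such an array was tested.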

How the results depend on the processing

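The fits with gain as a block, with saline as 3 averages, without doubtful arrays and within scan days or gains were chosen after the result was seen. Where no cause is given, the cause was not tested. Slide was fitted as a fixed block in 1 of 6 comparisons only, and scan day in none of those with saline, because each batch there holds 1 group. Median signal over background was 5.12 to 11.7 per array, which limits small changes.

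Scaling moved the counts between treated groups. With normexp 10770 probes passed for high-dose against low-dose SXC, 14543 for valsartan against low-dose SXC and 17 for valsartan against high-dose SXC. With quantile normalisation the last count was 728. Lists called for the SXC doses were 0 by camera with quantile normalisation and in the authors' values (8 at an unadjusted p under 0.05 in each), and 2 for valsartan against low-dose SXC in each. Of 314 results for named genes, 283 were the same with normexp, 297 with quantile normalisation, 296 in the authors' values, 297 with the replicate block and 276 with slide as a random block.

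With no filter on dim probes 10252, 13259 and 189 passed for the SXC doses, valsartan against low-dose SXC and valsartan against high-dose SXC. On probes well above background on all arrays, where fewer are tested, the 6 counts were 4544, 4302 and 4946 for high-dose SXC, low-dose SXC and valsartan against saline, then 1520, 1991 and 54, and camera called 3, 5 and 5 lists, 0 and 0 (2 at an unadjusted p under 0.05 in each), and 1. With 1 probe per gene, fewer by construction, they were 7130, 5561, 7288, 2632, 2807 and 197.

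With slide as a random block 1617, 1840 and 4 passed between treated groups, and as a fixed block, with a single low-dose array on the shared slide, 16 with 5 lists for the SXC doses. Scan day as a block left 0 (165 at an unadjusted p under 0.05 by limma) and 8 lists for the SXC doses. For these doses that block rests on 2 arrays of each. It left 3 probes and 2 lists for valsartan against low-dose SXC. Gain as a block gave 6505 for high-dose SXC and 3256 for valsartan against saline, 0 (1014 at an unadjusted p under 0.05) with 5 lists for the SXC doses, 3 for valsartan against low-dose SXC and 1423 against high-dose SXC. Array weights gave 15621 for low-dose SXC against saline, 10081 for the SXC doses and 670 for valsartan against high-dose SXC, which the 2 groups alone gave as 4 and an unadjusted p with a 1.5-fold change as 2700. Camera with an estimated correlation called 0 lists in all 6 comparisons (6, 9, 6, 1, 0 and 0 at an unadjusted p under 0.05). It was run with no block only.

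The replicate block gave 108 probes for valsartan against high-dose SXC and 6 lists for the SXC doses. The replicate numbers do not pair the arrays: 6 of 36 pairs of a number across groups had r above 0.1 (range -0.364 to 0.281).

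Leaving out arrays moved counts both ways. Saline as 3 averages gave 5708 for low-dose SXC. Without the lower-gain arrays limma called 0 for the SXC doses (2320 at an unadjusted p under 0.05), as it did on scan day 1 alone (477). For valsartan against high-dose SXC 1255 passed without arrays having under 50% of probes above background, 5 on scan day 3 alone and 4 on lower-gain arrays alone. Without saline 4 and 8 the counts against saline were 12349, 8225 and 12642.

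Leaving out 1 array at a time gave 12588 (high-dose 4) to 13816 (high-dose 1) for high-dose SXC against saline, 8385 (low-dose 6) to 9275 (saline 5) for low-dose SXC and 13062 (valsartan 5) to 13899 (valsartan 4) for valsartan. The SXC doses gave 3357 (high-dose 4) to 7148 (high-dose 1), valsartan against low-dose SXC 4622 (low-dose 2) to 6229 (valsartan 4), and valsartan against high-dose SXC 92 (valsartan 6) to 886 (valsartan 1).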

Other observations

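The receptor, channel, olfactory and fat gene results in this part were chosen after the results were seen. Genes of the vasoactive list, picked from it here, went in both directions. The alpha 1A adrenoceptor gene Adra1a rose by 3.89, 2.31 and 3.65 with high-dose SXC, low-dose SXC and valsartan against saline, Adra1d by 1.02, 1.36 and 1.05, and the CGRP receptor partner Ramp1 by 1.33, 1.57 and 1.42. The endothelin converting enzyme Ece1 fell by 1.92, 1.78 and 1.64, and the endothelin B receptor Ednrb by 3.09 and 3.21 with high-dose and low-dose SXC, being well above background on 0 of 6 valsartan arrays. Of 30 measured genes of the vasoactive list, 6, 8 and 10 rose (6, 9 and 11 adjusted over the list alone) and 11, 11 and 13 fell, and the list was not called (adjusted p = 0.268, 0.397 and 0.334).

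Of 21 calcium handling and potassium channel genes 10, 10 and 12 rose against saline and 2, 2 and 1 fell, and camera did not call the list (adjusted p = 0.554, 0.0659 and 0.104). The risers included the IP3 receptor Itpr1 (0.62, 1.14 and 0.79), the cation channel Trpc1 (0.63, 1.13 and 1.09), the ATP-sensitive potassium channel Kcnj8 (0.55, 0.75 and 0.90) and phospholamban, Pln (0.86, 0.82 and 1.07). Trpc6 fell with SXC (-1.93 and -1.14), and its fall with valsartan (-2.12) turned to 0.04 after normexp.

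Olfactory receptor probes made up 1127 probes, of which 397 were tested. Of these, 333 were higher with high-dose SXC (83.9%), 116 with low-dose SXC (29.2%) and 302 with valsartan (76.1%) than in saline, and 1, 7 and 6 were lower. The medians were 2.33, 0.64 and 2.05, staying positive after normexp (1.57, 0.53 and 1.75), quantile normalisation (1.44, 0.46 and 1.02) and in the authors' values (1.52, 0.45 and 1.05). The counts moved more: 385, 135 and 386 were higher after normexp, 236, 83 and 200 after quantile normalisation (12, 6 and 25 lower) and 236, 81 and 198 in the authors' values (11, 6 and 24 lower). Of all such probes 17.7% to 30.4% were well above background on saline arrays, 27.0% to 37.4% on low-dose arrays, 8.90% to 43.1% on high-dose arrays and 8.56% to 26.4% on valsartan arrays, so that this share did not follow the rise. The 75th percentile that levels are taken against was 1187 to 1440 on saline arrays and 945 to 1274 on low-dose arrays. It was 327 to 1246 on high-dose arrays and 289 to 648 on valsartan arrays. After this scaling the lowest level was -8.94 on saline array 1, -8.20, -9.02 and -8.83 on low-dose arrays 1 to 3, -3.37 on high-dose array 3 and -5.71 on valsartan array 6. A higher floor can make faint probes read higher on such arrays, though these low-dose arrays had none. How much of the rise comes from this, and whether the signal is expression of the receptors, was not tested.

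Fat genes varied among the saline arrays in pairs of arrays. Adipoq was 2.05 and 2.06 on arrays 1 and 5, 4.31 and 4.36 on arrays 2 and 6, and 6.22 and 6.27 on arrays 3 and 7, with 3.58 on array 4 and 5.55 on array 8. Ucp1 was 1.62 and 0.25, 3.58 and 2.82, and 6.91 and 6.49 on the same pairs, 2.91 on array 4 and 6.14 on array 8. After each slide's mean was taken off, the pairs correlated with r = 0.71, 0.66 and 0.87 across probes, and arrays 4 and 8 with -0.04. The 8 saline arrays may therefore hold fewer than 8 independent samples, and with saline as 3 averages 9780, 5708 and 9920 probes passed.

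Camera called 12 of the 33 lists in 0 comparisons, with a lowest adjusted p of 0.0679 to 0.702: synthetic smooth muscle, TGF-beta, vasoactive, skeletal muscle, cardiac muscle, nerve, immediate early, unfolded protein response, NADPH oxidase, aryl hydrocarbon receptor, cholesterol synthesis and glycolysis genes.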
